A study of Mus musculus with 4 samples.

How the data were processed

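The series holds 4 Affymetrix mouse expression arrays of colonic intestinal epithelial cells, 1 array for each of 4 genotypes: wild type, loss of Bmi1 in intestinal epithelium, loss of Mel18 (gene symbol Pcgf2) in intestinal epithelium, and loss of both. Per the labels' protocols, sex-matched C57BL/6 mice of 6 to 8 weeks received azoxymethane at 10 mg/kg and, 5 days later, 3.5% dextran sulfate sodium in drinking water for 5 days, a model of colitis-associated colorectal cancer. Cells were shaken off the opened colon with EDTA on day 12 without a sorting step in the protocol, and 200 ng of Trizol-extracted total RNA was labelled per array. The labels do not state how many mice went into an array. The series description puts 1 after the double knockout, 3 after Bmi1, 2 after Mel18 and 4 after wild type without saying whether these count mice or number the samples, so pools of unlike size are not ruled out.

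The deposited values are intensities per probe set, which the authors made with Affymetrix Expression Console and RMA per the submitters' processing notes. No version is given there, and whether the 4 arrays were summarised together is not given in the sources used here. The table holds them on a linear scale, from 3.25 to 22803 intensity units, whereas the design written before the data were examined spoke of log2 values. Log2 of each intensity was therefore taken, without a pseudocount, and no other scaling was applied. Medians of the arrays were 34.2 (wild type), 32.1 (Bmi1), 32.9 (Mel18) and 34.1 (double knockout) intensity units.

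The table has 45037 probe sets, of which 34945 had exactly 1 gene symbol in the platform annotation, 932 had several and 9160 were not listed there and are unnamed here. For 34741 of the probe sets with 1 symbol the gene identifier matched the current mouse gene table of assembly GRCm38.p6, from which symbols were updated and gene neighbours were taken. Each of 18193 genes was represented by its probe set with the highest mean over the 4 arrays. The floor was the median of all probe-set values, 33.4 intensity units, and 12154 genes reached it on at least 1 array. No Affymetrix control probe sets occur in the table.

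With 1 array per genotype there is no replicate, so no p-value, standard deviation or standard error across arrays is given anywhere, and the number of arrays limits the precision of every value. A gene counts as higher or lower in a comparison when it differed at least 2-fold and its higher value reached the floor. The comparisons were 3 of a knockout array with wild type and 2 of the double knockout with each single knockout. The difference for each gene's loss on the wild-type background shares no array with the difference on the other knockout's background, and the overlap of those lists is given beside the overlap of independent lists of the same sizes. A gene is called non-additive when the double-knockout value minus both single-knockout values plus the wild-type value was at least 1 in size on the log2 scale. Correlations are across genes, which are not independent replicates, and for differences that share the wild-type array the value simulated for unchanged arrays is given beside them. That simulation took the noise SD of the closest pair of arrays, 0.23, so its covariances are the lowest the pairs would give.

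Before the data were examined, 39 gene lists were fixed, covering Polycomb complexes, signalling and metabolic pathways, epithelial cell types, other cell types the preparation could hold, and housekeeping genes. The median log2 difference of the members at or above the floor was set against 10000 random lists of the same size matched on mean expression in 20 bins, and a list below percentile 2.5 or above percentile 97.5 stands apart. This describes these arrays and is no test of a genotype. Lists with fewer than 5 such members were left out, which removed the erythroid list (3 members) and the sex-linked list (4 members). If the 37 remaining lists were genes drawn at random, 1.85 of them would stand apart in a comparison. Members of a fixed list may vary together and some lists share members, so this number is no bound for the lists used here.

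The genes named in the text were chosen by rules fixed before the data were examined. These take every probe set of Bmi1 and Pcgf2, the 12 highest and 12 lowest genes of each comparison with wild type, 8 genes per direction for each loss on both backgrounds, 5 genes per direction by non-additive term, the Reg family, and up to 4 members of each list with the largest differences together with members that show its range. Genes past the size rule on all 3 knockout arrays were added to the named genes after their values were seen. Systematic clone and predicted-gene names were counted and not named.

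Alternatives were the mean over all probe sets of a gene, no floor, a floor at percentile 75, centring each array on its median, quantile normalization, a 1.5-fold rule, leaving out probe sets of the types that can hybridise to several transcripts, and list means in place of medians. Centring each array on the median of the genes at or above the floor was added after seeing the data. The rules were tested on simulated arrays of the same 18193 genes, with the changes placed on the double-knockout array and compared with wild type. The noise SD of 0.23 per array on the log2 scale came from the closest pair, Bmi1 and Mel18, whose differences had an SD of 0.32. Differences of the double knockout from wild type had an SD of 0.49, real changes included. The shares that follow are thus for the lowest noise among the pairs and may be too favourable. In the simulation, 90% of 50 genes changed 2.5-fold and 98% of 50 genes changed 4-fold were called, as were 4% of 50 genes changed 1.5-fold and 0.14% of 17993 unchanged genes. The changed genes were drawn only from those with a mean at least 2-fold above the floor. The unchanged genes included those under the floor, which can hardly be called. For genes near or under the floor these shares may thus be too favourable as well. Of 200 unchanged lists 6% stood apart, and 91.5% of 200 lists shifted by 0.3 did. That last share came from 200 lists because a first run with 20 lists fell short of the preset requirement of more than 80%. The requirement was eased in between to a shift of 0.5 and then put back, and the share given is the one under the preset requirement. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.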

Results

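Colonic epithelial cells were profiled on day 12 of an azoxymethane and dextran sulfate sodium model, in which a carcinogen is followed by a chemical colitis that leads to colon tumours. The design compares loss of Bmi1, loss of Mel18 and loss of both, which are related subunits of Polycomb repressive complex 1, a chromatin complex that keeps developmental genes and the Cdkn2a locus silent. One array was hybridised for each of the 4 genotypes, so every value below is from 1 array and no difference has a replicate check. Values are RMA intensities, and differences are on the log2 scale. Where 1 of the values compared lies under the floor of 33.4 units, as for many of the largest differences, the size of the difference and its rank may depend on background signal and are not exact.

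The targeted genes were read first. Both Bmi1 probe sets were brighter on the arrays whose label includes Bmi1 loss: the first read 116 units on the wild-type array, 334 on the Bmi1-labelled array, 160 on the Mel18-labelled array and 432 on the double-knockout-labelled array, and the second read 88.4, 339, 135 and 399. Pcgf2, which encodes Mel18, lay near or under the floor of 33.4 on every array with its brighter probe set at 30.2 in wild type and 39.8 on the Mel18-labelled array, and it was not lower by the size rule on the Mel18-labelled arrays. The deleted exons and the probes' places in them are not given, so neither gene checks a label, the Bmi1 values go against a loss of its transcript, and the arrays are called by their labels throughout. Xist, the transcript of the inactive X chromosome, read 122 on the wild-type array, 45.5 and 54.2 on the Bmi1-labelled and Mel18-labelled arrays and 611 on the double-knockout-labelled array, while the Y-linked Eif2s3y read 246, 282, 198 and 229. The labels call the mice sex-matched, but the sexes behind each array are not given, and a difference in them would run with every comparison.

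The closest pair of arrays was the Bmi1-labelled and Mel18-labelled pair, with a Spearman correlation across probe sets of 0.990 and 164 genes at least 2-fold apart. The wild-type and double-knockout-labelled arrays followed at 0.984 with 512 genes apart, and the Bmi1-labelled and double-knockout-labelled arrays were the farthest pair at 0.969 with 1468 genes apart.

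**Figure D1:**
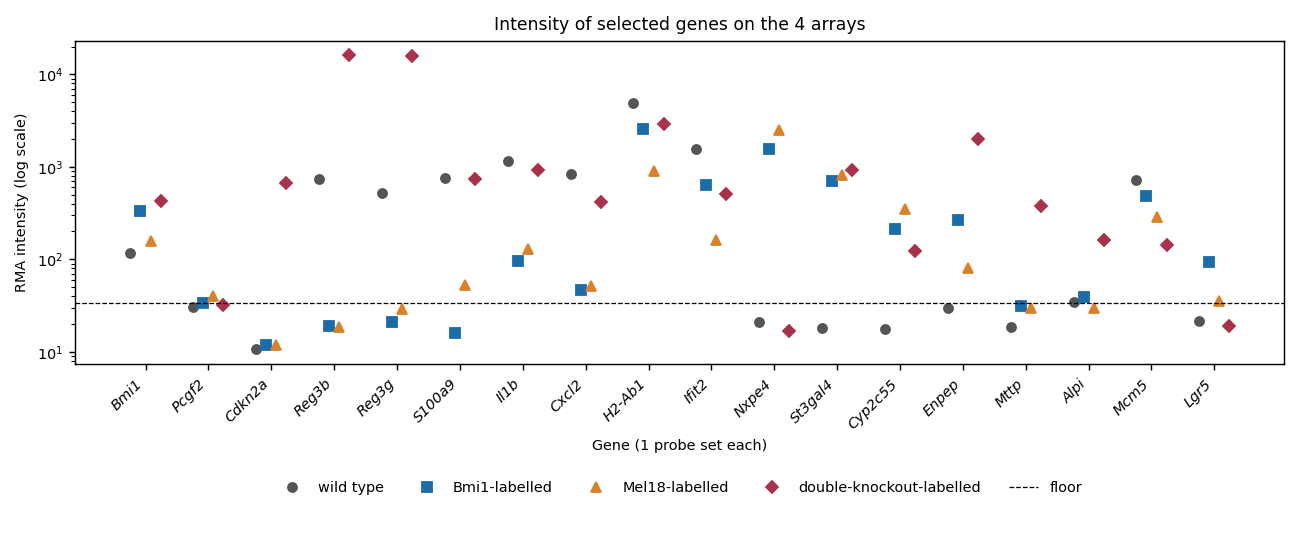
RMA intensity (log axis) of 18 named genes on the 4 arrays, 1 point per array, with the floor as a dashed line. Reg3b and Reg3g were far brighter on the double-knockout-labelled array than on both single-knockout arrays, where they lay under the floor, and Cdkn2a was above the floor on the double-knockout-labelled array alone.

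Inflammatory and antimicrobial transcripts were much lower on the Bmi1-labelled array than on the wild-type array, and many transcripts of xenobiotic metabolism and a few of colonic stem cells were higher. Reg3b and Reg3g, secreted lectins that kill bacteria at the epithelial surface, read 731 and 523 in wild type and 19.1 and 20.8 on the Bmi1-labelled array. S100a8 and S100a9, the calprotectin subunits abundant in neutrophils, read 935 and 762 in wild type and lay under the floor on the Bmi1-labelled array. In the other direction, Lgr5 and Smoc2, markers of intestinal stem cells, read 21.7 and 42.0 in wild type and 93.6 and 188 on the Bmi1-labelled array.

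By the size rule, 687 genes were higher and 341 lower, together 8.61% of the 11934 genes tested. Among the 12 lowest were Gbp2b, an interferon-inducible guanylate-binding protein, at -7.02, S100a9 at -5.58, Plet1 at -5.40, Reg3b at -5.26 and Lrg1 at -5.18. They also held Clca4b at -4.84, Retnlb, a goblet cell product induced by bacteria and helminths, at -4.52, the peroxidase Lpo at -4.52, the pseudogene Clca4c-ps at -4.52 and the neutrophil-attracting chemokine Cxcl2 at -4.17. The highest were Nxpe4 at 6.21, Hsd17b13 at 6.19, the sialyltransferase St3gal4 at 5.27, Ifi44l at 4.38, Tnfsf13os at 4.22 and the cytochrome P450 Cyp2c55 at 3.58. Ap1s3, the peptide transporter Slc15a2, the aminopeptidase Enpep, the gluconeogenic enzyme Pck1, Zan and the pyrimidine-degrading enzyme Dpyd completed the 12, between 2.98 and 3.52.

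Among the lists, the neutrophil list lay lowest with a median of -2.68, with 10 of its 14 members lower by the size rule and none higher. The inflammatory cytokine list had a median of -0.77, with 9 of 19 members lower, including Il1b at -3.59, Cxcl5 at -4.11 and Ptgs2, the inducible prostaglandin synthase, at -2.96. Antimicrobial and Reg genes had a median of -1.11, with 9 of 17 lower and Reg4 higher at 1.22. With arrays centred on the genes at or above the floor, Reg4 lay at 0.99 and did not pass the size rule. Of the macrophage and dendritic cell markers 11 of 21 were lower and none higher, among them Tyrobp at -2.01 and Fcgr3 at -1.69. Fibroblast markers lay at -0.99, with 10 of 24 lower, such as the collagens Col3a1 at -1.85 and Col1a2 at -1.34, although Fap was higher at 1.53. Smooth muscle markers lay at -0.52 with none of 14 past the size rule, T and NK cell markers at -0.37 with 2 of 19 lower, and adipocyte and skin markers at -0.76 with 2 of 9 lower. Endothelial markers at -0.03, B and plasma cell markers at -0.15 and enteric neuron and glia markers at -0.29 lay inside the random range.

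Interferon response genes had a median of -0.44 with 9 of 29 members lower, such as Oas2 at -1.85 and Rsad2 at -1.84, whereas Iigp1 read 0.20. Cholesterol synthesis genes lay at -0.52 with none of 15 past the size rule, and Fdps read -0.83 and Lss -0.79. Xenobiotic and steroid metabolism genes lay highest at 1.10, with 12 of 22 members higher, among them Hsd3b3 at 2.55 and Cyp11a1, which starts steroid synthesis, at 1.97. Wnt targets and stem cell genes lay at 0.59, with 3 of 23 members higher (Lgr5 2.11, Smoc2 2.16, Ascl2 1.54) and Prom1 lower at -1.14. Fatty acid and PPAR target genes lay at 0.45 with 6 of 20 higher, such as Acaa2 of mitochondrial fatty acid oxidation at 1.52, and Scd1, a desaturase, lower at -1.70. All of these lists stood apart from random lists, and in all 3 lists stood apart higher and 17 lower.

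The median gene at or above the floor differed by 0.12 on this array as deposited, by 0.21 with arrays centred on their medians and by -0.12 with arrays centred on their genes at or above the floor. The 66.8% of genes past the size rule that were higher became 76.1% and 38.2% under these 2 centrings, so the balance of the counts has no fixed direction.

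**Figure D2:**
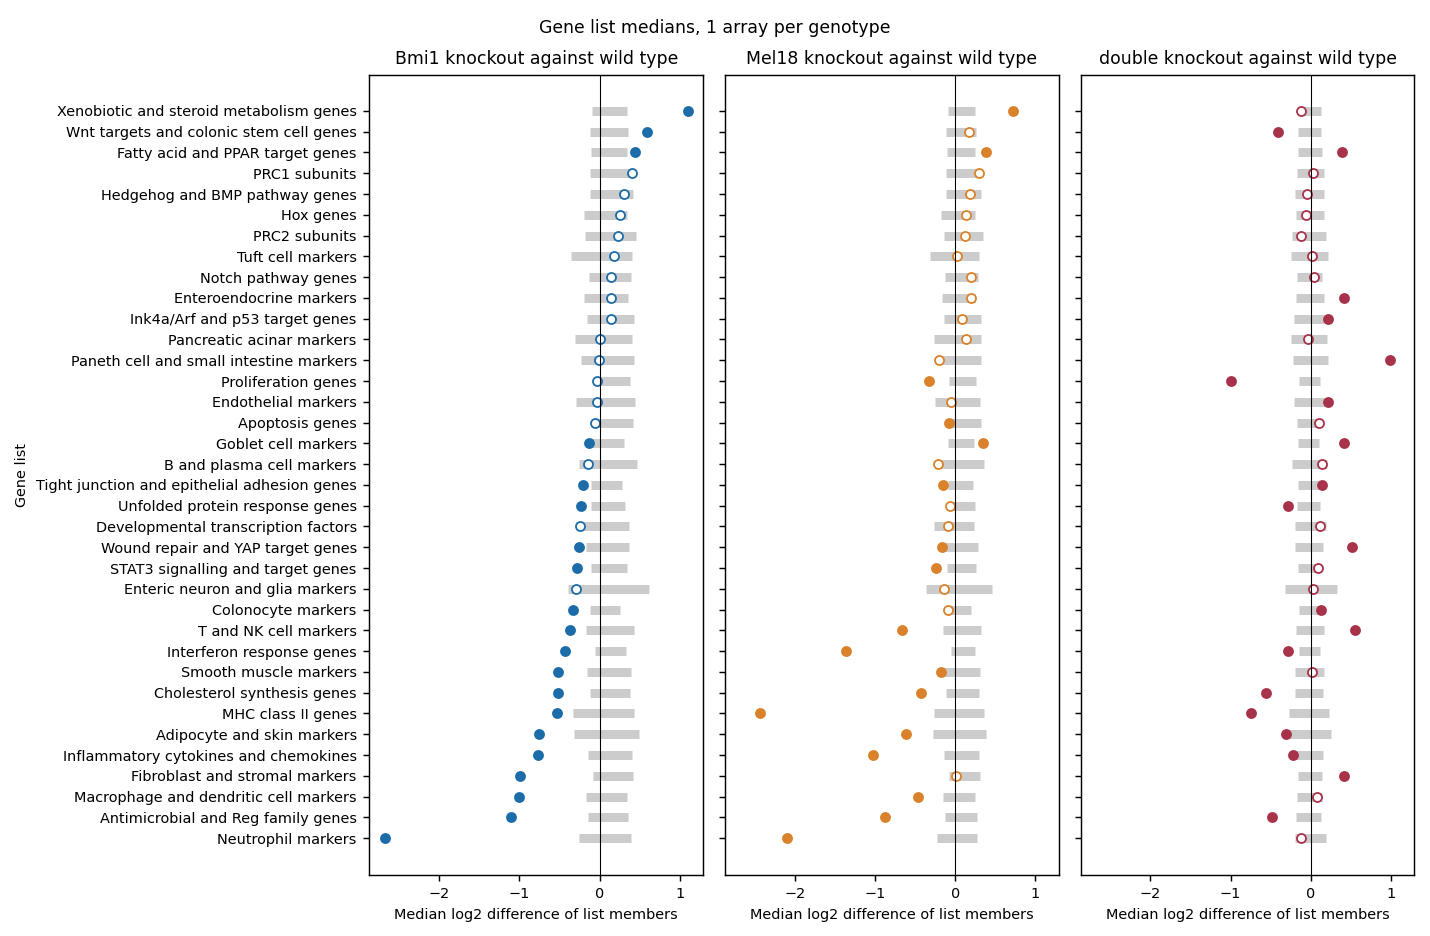
Median log2 difference against wild type (horizontal axis) of 36 gene lists (vertical axis) on the Bmi1-labelled, Mel18-labelled and double-knockout-labelled arrays. Grey bars span the central range of random matched lists, filled points lie outside them and open points inside; the neutrophil list lay at -2.68, -2.10 and -0.12 on the 3 arrays.

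On the Mel18-labelled array the same inflammatory transcripts were low, and interferon-induced and antigen-presentation transcripts were lower than on any other array. MHC class II genes, which present antigen to helper T cells, had a median difference of -2.43 from wild type, against -0.54 on the Bmi1-labelled array. Their master regulator Ciita read 196 in wild type and 22.5 here, and H2-Ab1 read 4882 and 906. Fibroblast markers did not stand apart on this array, with a median of 0.01, whereas adipocyte and skin markers at -0.61 (2 of 9 lower) and smooth muscle markers at -0.18 (none of 14 past the size rule) stood apart lower. The smooth muscle list did not stand apart by its mean (-0.13, percentile 6.45).

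By the size rule, 374 genes were higher and 296 lower. The 12 lowest again held Gbp2b at -6.26, with Reg3b at -5.30, Plet1 at -4.97, the platelet chemokine Ppbp at -4.74, Lpo at -4.30 and Reg3g at -4.18. Cxcl2 at -4.01, S100a9 at -3.85, Ubd, a ubiquitin-like protein induced by interferon gamma, at -3.81, Lrg1 at -3.68, lactoferrin (Ltf) at -3.58 and the protease Prss22 at -3.49 completed them. The highest were Nxpe4 at 6.89, St3gal4 at 5.49, Tnfsf13os at 4.68, Cyp2c55 at 4.31, Zan at 3.47 and Slc15a2 at 3.25. Pck1, Nxpe2, the pentraxin Mptx1, Hsd3b3, Dpyd and the esterase Aadac followed, from 3.20 down to 2.53.

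The MHC class II list had 7 of 7 members lower, and the interferon list, with a median of -1.36, had 18 of 29, including Ifit2 at -3.29 and the T cell chemokine Cxcl9 at -2.34. Neutrophil markers lay at -2.10 with 9 of 14 lower, and inflammatory cytokines at -1.02 with 10 of 19 lower, among them Il1b at -3.17 and Ccl7 at -3.20. Antimicrobial and Reg genes lay at -0.88 with 7 of 17 lower. T and NK cell markers lay at -0.66 with 6 of 19 lower, such as granzymes Gzmb at -1.68 and Gzma at -1.56, and macrophage markers at -0.47 with 4 of 21 lower. Proliferation genes lay at -0.32 with 3 of 28 lower, namely Rrm2, which supplies deoxynucleotides, at -1.73 and the replication helicase subunits Mcm5 at -1.31 and Mcm3 at -1.06. Xenobiotic genes were again highest at 0.73 with 6 of 22 higher, and goblet cell markers lay at 0.35 with 3 of 23 higher, such as Creb3l4 at 1.56 and Klk1 at 1.09. In all, 3 lists stood apart higher and 15 lower.

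The differences of the Bmi1-labelled and Mel18-labelled arrays from wild type correlated across genes at r = 0.85, with 285 genes higher on both (20.3 for independent lists) and 190 lower on both (8.56 for independent lists). They share the wild-type array, which alone gave 0.49 in simulation. The covariance was 0.28 against 0.05 simulated, but the simulated noise SD of 0.23 came from the closest pair, these same 2 arrays. That baseline is the lowest the pairs would give, so the size of the excess is not known. Part of it may not be separable from the shared array since wild type cannot be split. The share of genes past the size rule that were higher on the Mel18-labelled array was 55.8% as deposited and 36.6% with arrays centred on the genes at or above the floor.

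The double-knockout-labelled array shared some differences with the other knockout arrays and also differed from wild type in genes that stayed close to wild type on those. Cdkn2a, which encodes the cell cycle inhibitor p16 and the p53 activator Arf, read 662 there and between 10.6 and 11.9 on the other 3 arrays. Reg3b and Reg3g read 16063 and 15800.4, above their wild-type values of 731 and 523. Several Paneth cell and small intestine markers were higher, and many DNA replication and cell division transcripts were lower than wild type. Neutrophil markers, low on both single-knockout arrays, lay at -0.12, whereas interferon response genes stood apart lower at -0.28, with 3 of 29 lower.

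By the size rule, 253 genes were higher and 259 lower. The highest were Enpep at 6.06, Tm4sf5 at 5.99, Cdkn2a at 5.97, St3gal4 at 5.70, Reg3g at 4.92 and Naaladl1 at 4.83. The pantetheinase Vnn1 at 4.66, Reg3b at 4.46, Mttp, which loads lipid onto apolipoprotein B, at 4.33, Depdc7 at 4.26, Cyp2c65 at 4.24 and sulfite oxidase (Suox) at 3.96 completed the 12. Pla2g2a, a secreted antimicrobial phospholipase, was among the 12 lowest at -3.91, with Plet1 at -3.29, Ccl7 at -3.26, Smpx at -3.09, Lrg1 at -3.00 and Slc37a2 at -2.91. Cbr2, Shisa2, Defb45, the serotonin receptor Htr4, Cpne8 and the transglutaminase Tgm3 followed, from -2.82 to -2.67.

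Proliferation genes had a mean difference of -1.12, with 14 of 28 members lower and none higher, including Mcm5 at -2.32, Mcm6 at -2.28 and Rrm2 at -2.15. Paneth cell and small intestine markers lay at 0.99 with 6 of 12 higher, among them the ileal bile acid transporter Slc10a2 at 2.96, intestinal alkaline phosphatase (Alpi) at 2.24, the small-intestinal transcription factor Gata4 at 2.03 and the ileal bile acid binding protein Fabp6 at 1.14, while Ang4, a Paneth and goblet cell product, was lower at -2.29. Ink4a/Arf and p53 target genes lay at 0.21, with 3 of 14 higher, namely Cdkn2a, Cdkn2b at 1.54 and Phlda3 at 1.02. Wound repair and YAP target genes lay at 0.51 with 4 of 15 higher, namely Il33 at 2.73, Ereg at 1.30, F3 at 1.26 and Plaur at 1.12. Enteroendocrine markers lay at 0.42 with 6 of 19 higher, such as cholecystokinin (Cck) at 2.38 and somatostatin (Sst) at 1.33. T and NK cell markers lay at 0.55 with 5 of 19 higher, such as Gzma at 1.75, and fibroblast markers at 0.41 with 2 of 24 higher. Goblet cell markers lay at 0.42 and colonocyte markers at 0.13. Of the 25 colonocyte markers 7 were higher, such as the peptide hormone Guca2a at 2.41 and carbonic anhydrase Car1 at 1.45, and 3 were lower, such as the water channel Aqp8 at -1.43.

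Wnt targets and stem cell genes lay at -0.40 with 4 of 23 lower, among them Cdca7 at -1.79 and Axin2 at -1.12, although Sox9 was higher at 1.68. MHC class II genes lay at -0.75 and cholesterol synthesis genes at -0.56, with none past the size rule in either list. Antimicrobial and Reg genes had a median of -0.48 although Reg3b and Reg3g were higher, with 4 of 17 lower, and this list no longer stood apart by its mean (-0.19, percentile 5.33) or without a floor (percentile 3.47). Inflammatory cytokines lay at -0.23 (percentile 0.64) with 4 of 19 lower and 2 higher, but inside the random range without a floor (percentile 47.34), with the floor at percentile 75 (3.68), with the mean over probe sets (3.27) and by the list mean (2.51). In all, 11 lists stood apart higher and 9 lower. The neutrophil list stood inside the random range, at percentile 11.1, but below it without a floor, at percentile 1.25, and by its mean of -0.28, at percentile 1.49.

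Across the 3 knockout arrays, 51 genes were higher than wild type on every one and 41 were lower. The higher set held St3gal4, Slc15a2, Cyp2c55, Cyp2c65, Enpep, the metallothioneins Mt1 and Mt2, the growth hormone receptor Ghr and the cytokine Il15. St3gal4 read 18.0 in wild type and 696, 808 and 935 on the Bmi1-labelled, Mel18-labelled and double-knockout-labelled arrays. The lower set held Plet1, Lrg1, the oncostatin M receptor Osmr, the acute-phase protein Saa3, the heat shock genes Hspa1a and Hspa1b, and the monocyte chemokines Ccl2, Ccl7 and Ccl8. Osmr, the receptor for a cytokine of gut inflammation, differed by -2.36, -2.50 and -2.56 in that order. Across genes, the difference of the double-knockout-labelled array from wild type correlated at 0.18 with that of the Bmi1-labelled array and at 0.26 with that of the Mel18-labelled array, below the 0.50 and 0.51 simulated for a shared wild-type array alone. Their covariances were 0.06 and 0.07 against 0.05 simulated for each at the noise of the closest pair of arrays. On both arrays of the first pair 72 genes were higher and 48 lower (10.7 and 7.57 for independent lists), and 64 and 54 in the second (5.71 and 6.57). Genes in opposite directions also outnumbered those of independent lists. In the first pair 27 were higher on the Bmi1-labelled and lower on the double-knockout-labelled array, and 10 the reverse (12.96 and 6.254). In the second pair these counts were 12 and 11 (7.076 and 5.298). The excess over independent lists was thus not confined to a shared direction. The genes past the size rule on all 3 knockout arrays, 51 higher and 41 lower as deposited, numbered 30 and 26 with the floor at percentile 75 and 37 and 30 with the mean over probe sets. They numbered 34 and 48 with arrays centred on the genes at or above the floor and 209 and 127 under the 1.5-fold rule. Under alternatives looked at after the result, Slc15a2, Ghr and Osmr left these sets with the mean over probe sets, Cyp2c55, Cyp2c65, Enpep and Ccl2 with the floor at percentile 75, Cyp2c65 and Ghr without the probe sets that can hybridise to several transcripts, and Mt1 and Il15 with arrays centred on the genes at or above the floor. All 3 differences share the wild-type array, so a high or low value on that array alone would place a gene in these sets.

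Loss of each gene was then compared on 2 backgrounds, from arrays not shared between the differences. Both differences come from the same 4 arrays as the comparisons above, so their relation is fixed by those and is no separate evidence. By arithmetic, the covariance of the 2 Bmi1 differences (-0.226) follows from 2 covariances of differences from wild type. These are Bmi1-labelled with double-knockout-labelled (0.055), less Bmi1-labelled with Mel18-labelled (0.281). Opposite directions thus restate that the 2 single-knockout arrays lay close together, for Mel18 as for Bmi1. For Bmi1, the difference from wild type and the difference of the double-knockout-labelled from the Mel18-labelled array ran in opposite directions across genes, with r = -0.58. Between the double-knockout-labelled and Mel18-labelled arrays 456 genes were higher and 538 lower, and MHC class II genes, at a median of 1.68, and neutrophil markers, at 1.59, stood apart higher. Genes higher on both backgrounds numbered 19, against 23.0 for independent lists, and included Enpep (3.14 and 4.62), Ifi44l (4.38 and 2.93), the urea cycle enzyme Otc (1.72 and 1.78), Cyp2c65, Ces1c, the apolipoprotein Apoc2, the calcium-binding S100g and Bmi1 itself (1.53 and 1.44). Lower on both were 3 genes, against 14.5 for independent lists: Pla2g2a (-2.23 and -2.98), the proton pump Atp12a (-1.23 and -1.57) and Cpne2 (-1.23 and -1.02). In opposite directions, 203 genes were higher on wild type and lower on the Mel18 background (30.0 for independent lists), and 142 were the reverse (11.1).

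For Mel18, the difference from wild type and the difference of the double-knockout-labelled from the Bmi1-labelled array correlated at r = -0.56. Between the double-knockout-labelled and Bmi1-labelled arrays 515 genes were higher and 953 lower, fibroblast markers lay at a median of 1.34 and proliferation genes at -1.05. On both backgrounds 10 genes were higher, against 14.9 for independent lists, among them Cyp2c65 (2.12 and 2.58), Naaladl1 (1.78 and 3.81), Enpep (1.44 and 2.92), Slc7a9, Mptx1, Paqr8, Rps4l and Nags. Another 10 were lower, against 21.5, among them Cxcl9 (-2.34 and -1.38), the replication genes Mcm5 (-1.31 and -1.75) and Mcm3, the DNA repair gene Brca1, Iigp1, Gdpd3, Clca3b and Atp12a. Of these, Paqr8, Nags, Mcm5, Mcm3, Brca1, Clca3b and Atp12a no longer passed the size rule on the Mel18-labelled array under at least 1 alternative. Of the genes past the size rule, 45.9% were higher in the first of these comparisons and 35.1% in the second as deposited, 62.8% and 61.4% with arrays centred on the genes at or above the floor, and 27.4% in the second with arrays centred on their medians.

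**Figure D3:**
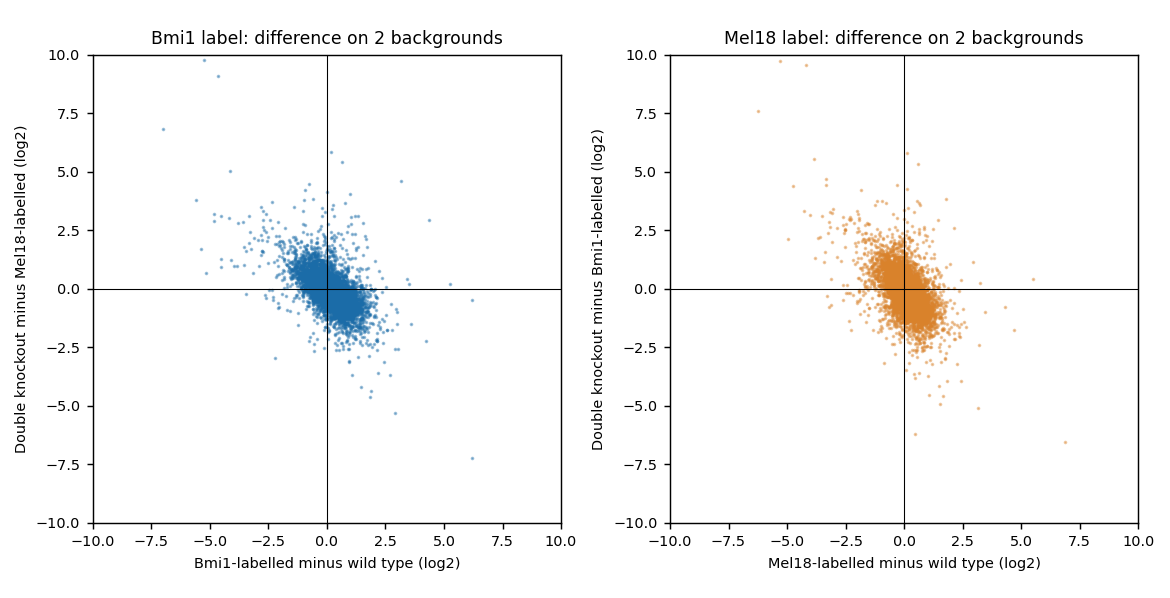
Log2 differences of 12154 genes, 1 point per gene, for the Bmi1 label (left) and the Mel18 label (right), on the wild-type background (horizontal axis) and on the other knockout's background (vertical axis). Points run from upper left to lower right in both panels, with r = -0.58 and r = -0.56.

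By the sum of the 4 arrays, 3322 of 12154 genes were non-additive, 1058 with a positive and 2264 with a negative term. The balance of signs has no fixed direction, as 2026 were positive and 1196 negative with arrays centred on the genes at or above the floor, where the median term was 0.20 against -0.21 as deposited. Reg3b at 15.0, Gbp2b at 13.9, Reg3g at 13.8, S100a9 at 9.37 and Ppbp at 9.14 were the 5 genes taken with high terms, being low on both single-knockout arrays and high on the wild-type and double-knockout-labelled arrays. Nxpe4 at -13.4, Nxpe2 at -8.23, Hsd17b13 at -6.68, Smpx at -6.46 and Tnfsf13os at -6.44 were the 5 with low terms. Nxpe4 read 1561 and 2496 on the Bmi1-labelled and Mel18-labelled arrays and 21.1 and 16.6 on the wild-type and double-knockout-labelled ones. Reg3b, Gbp2b and Reg3g lay under the floor on both single-knockout arrays, so the sizes and the order of these terms are not exact. A term built from 4 arrays carries the noise of all 4, and the size rule is the one used for a difference of a pair.

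Among genes with several probe sets, the median SD between their differences was 0.24 on the Bmi1-labelled, 0.21 on the Mel18-labelled and 0.17 on the double-knockout-labelled array. Some named genes rest on 1 of several disagreeing probe sets: for Hsd17b13 they read from -0.04 to 6.19 on the Bmi1-labelled array, for Slc15a2 from -0.59 to 3.42, for Dpyd from -0.11 to 2.98, for Pck1 from 0.03 to 3.06, for Tnfsf13os from 0.16 to 4.22, for Ifi44l from 0.78 to 4.38, for Osmr from -2.36 to -0.02, for Lgr5 from -0.06 to 2.11 and for Plet1 from -5.40 to -0.67, while those of Reg3b read -5.76 and -5.26. On the Mel18-labelled array those of Cxcl9 read from -2.34 to -0.20 and those of Brca1 from -1.04 to 0.15, and on the double-knockout-labelled array those of Htr4 read from -2.68 to 0.61 and those of Mcm5 from -2.32 to -0.46.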

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

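The results below were picked out because the difference for a gene's loss took opposite directions on the 2 backgrounds, or because a signal lay outside the named genes. With 1 array per genotype none of these differences was tested. The tests on the share of non-epithelial cells, on a shared batch, on carry-over of small intestine and on developmental genes were chosen after the results were seen.

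For 17 lists the direction turned between backgrounds for at least 1 of the losses. As for the genes, this restates how the 4 arrays lie to each other and is no separate evidence. The value given is the median non-additive term. It was 4.34 for neutrophil markers, 2.23 for MHC class II genes, 1.98 for inflammatory cytokines, 1.60 for macrophage and dendritic cell markers, 1.53 for T and NK cell markers, 1.44 for antimicrobial and Reg genes and 1.41 for fibroblast markers. It was 1.26 for interferon response genes, 1.19 for wound repair and YAP targets, 0.95 for adipocyte and skin markers, 0.70 for colonocyte markers, 0.67 for smooth muscle markers, 0.53 for STAT3 targets, 0.51 for tight junction genes and 0.22 for goblet cell markers. By the list mean 3 of these calls against wild type end, for goblet cell markers on the Bmi1-labelled array (percentile 2.54) and for smooth muscle markers (6.45) and tight junction genes (4.83) on the Mel18-labelled array, and that of wound repair and YAP targets on the Mel18-labelled array ends with the floor at percentile 75 (5.39) and without the probe sets that can hybridise to several transcripts (2.58). Xenobiotic and steroid metabolism genes had -2.12 and Wnt targets and stem cell genes -0.91.

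The genes with the largest terms were Reg3b (15.0), Gbp2b (13.9), Reg3g (13.8), S100a9 (9.37) and Ppbp (9.14), and in the other direction Nxpe4 (-13.4), Nxpe2 (-8.23), Hsd17b13 (-6.68), Smpx (-6.46) and Tnfsf13os (-6.44). Among probe sets without a single gene name, which no comparison used, 73 were at least 2-fold higher on the double-knockout-labelled array than in wild type, against 102 on the Bmi1-labelled and 67 on the Mel18-labelled array.

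Immune and inflammatory transcripts were lower on both single-knockout arrays. A lower share of all non-epithelial cells would bring every such marker list down together. On the Mel18-labelled array the fibroblast median lay 2.11 above the neutrophil median (SE 0.65 from resampled members, not samples). A lower share is argued against as the whole cause on that array only, where smooth muscle (-0.18) and adipocyte and skin markers (-0.61) were also lower. On the Bmi1-labelled array fibroblast (-0.99), smooth muscle (-0.52), T and NK cell (-0.37) and adipocyte and skin markers (-0.76) fell with neutrophil markers (-2.68). Macrophage and dendritic cell markers fell there too (11 of 21 lower). Endothelial, B and plasma cell, and enteric neuron and glia markers stayed inside the random range. A lower share thus stays open for the Bmi1-labelled array. A scale difference left between the deposited arrays is also argued against, since after quantile normalization the neutrophil median stayed at -2.06 on the Mel18-labelled and -2.67 on the Bmi1-labelled array. Scaling within RMA itself cannot be undone from the deposited values and was not tested. A processing batch shared by these 2 arrays cannot be told apart from genotype: they were the closest pair, at 0.990, which either would give. A milder colitis in the mice behind these arrays and an effect of either genotype may each account for the pattern and remain untested. Fewer neutrophils may account for a part of it, which was not tested either. MHC class II genes lay at -2.43 (7 of 7 lower) on the Mel18-labelled and -0.54 (1 of 7 lower) on the Bmi1-labelled array. Macrophage and dendritic cell markers had 4 and 11 of 21 lower in that order. These falls argue against fewer neutrophils as the whole cause.

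Several small-intestinal transcripts were gained on the double-knockout-labelled array. Carry-over of small intestine cannot be told apart from expression in colon, because 3 of the 6 markers under the floor in wild type (Defa3, Lct and Olfm4) stayed under it, but no array of small intestine gives the level they would need. A more proximal stretch of colon stays open, since Hox genes of groups 9 to 13, which mark posterior gut, had a median of -0.33 against wild type (percentile 0.42) and 7 of 10 were lowest on this array, yet Hox genes are themselves Polycomb targets. A release of developmental genes under Polycomb control may contribute and is not settled either: 3 of 58 fixed transcription factors (Gata4, Pax3 and Irx2) were 2-fold higher, a number that 97 of 10000 random lists reached, but the list's median lay at percentile 89.9 and its mean at percentile 99.55. Only 17 of the 58 reached the floor on at least 1 array, and the median and mean are of those 17. Gata4 also belongs to the small-intestine list, as Alpi does to the colonocyte list, and an effect of the double loss remains untested.

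Some genes went from under the floor to at least 8-fold higher, or the reverse: 23 on the Bmi1-labelled, 18 on the Mel18-labelled and 19 on the double-knockout-labelled array, among them Nxpe4, St3gal4, Gbp2b and Cdkn2a. In that order of arrays 8, 6 and 17 of them were gained against wild type, and 15, 12 and 2 were lost. A chromosome segment carried along with a targeted allele stays open. Of these genes, 44 when each is counted once, 0 lay within 100 measured genes of Bmi1 or Pcgf2, a count chosen after a first result. The share planned beforehand was 0% at both loci (percentiles 41.95 and 40.9 of random windows). Neither figure can decide, because the median random window held none either. Outside that window but on the chromosome of a targeted locus lay 0 of the 23 genes of the Bmi1-labelled array, 1 of the 18 of the Mel18-labelled array and 3 of the 19 of the double-knockout-labelled array. A difference under a single probe set stays open: 83.3% of the 12 other probe sets at or above the floor on a compared array moved at least 2-fold the same way, but that filter, set beforehand, drops probe sets that stay under the floor, and of all 27 other probe sets 40.7% moved so, a share added after the result. A strain difference elsewhere in the genome was not tested and may account for part of the set, and an effect of genotype remains untested as well.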

How the results depend on the processing

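No paired analysis was possible because each genotype has 1 array, and leaving out replicates was not possible for the same reason. Values under the floor may hold background signal. How much is not known, because the floor is the median of all probe-set values and no background was measured. Centring on the genes at or above the floor was chosen after seeing the data. Of 134 alternative values of the main counts and correlations, 105 stayed within 1.5 times the count or close to the correlation, and 29 moved. A count cannot change sign, and neither correlation did. Of 867 list values 55 moved, which here means that a list came to stand apart or ceased to. No list that stood apart as deposited changed sign. A change of sign in a list inside the random range was not counted. Of 1059 named-gene differences 39 moved, and none changed sign.

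With the mean over probe sets, 169 genes were lower on the double-knockout-labelled array than in wild type, 349 lower after Bmi1 loss on the Mel18 background and 5 lower after Mel18 loss on both backgrounds. With the floor at percentile 75, which admits fewer genes, 440 were higher on the Bmi1-labelled array, 243 higher and 195 lower on the Mel18-labelled array, 155 lower on the double-knockout-labelled array, 8 higher after Bmi1 loss on both backgrounds and 5 higher after Mel18 loss on both. The 1.5-fold rule, looser by construction, gave 2128 higher and 899 lower (Bmi1 label), 1402 and 745 (Mel18 label), 726 and 777 (double knockout), 1024 and 1680 (Bmi1 loss on the Mel18 background), 1187 and 2553 (Mel18 loss on the Bmi1 background), 54 and 16 (Bmi1 loss on both), 51 and 54 (Mel18 loss on both) and 6096 non-additive genes. With arrays centred on the genes at or above the floor, 347 were higher and 562 lower on the Bmi1-labelled array, 234 higher and 406 lower on the Mel18-labelled array, and 826 higher and 519 lower after Mel18 loss on the Bmi1 background. The larger side turned in all 3 of these and after Bmi1 loss on the Mel18 background (615 higher, 364 lower). Of the genes named for Mel18 loss on both backgrounds, Paqr8 (0.29), Mcm5 (-0.87), Mcm3 (-0.77) and Brca1 (-0.36) no longer passed the size rule on the Mel18-labelled array with the mean over probe sets, Mcm3 (-0.86) without the probe sets that can hybridise to several transcripts, Atp12a (-0.97), Brca1 (-0.98) and Clca3b (-0.95) with arrays centred on their medians, Brca1 (-0.99) after quantile normalization and Nags (0.99) with arrays centred on the genes at or above the floor. The cause was not tested for these genes, for the probe-set mean or for this centring.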

Other observations

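Most apoptosis genes did not pass the size rule: of 20, 2 were higher and 1 lower on the Bmi1-labelled array, 1 and 2 on the Mel18-labelled array and 1 and 2 on the double-knockout-labelled array. The list lay at -0.05 (percentile 2.61, and below 2.5 under several alternatives, such as 1.94 without a floor), -0.08 (percentile 1.80, but 5.20 by its mean) and 0.11 (inside the random range). Ripk3, a kinase of necroptosis, read 382 in wild type, 108 on the Bmi1-labelled, 124 on the Mel18-labelled and 461 on the double-knockout-labelled array. Bmf, a pro-apoptotic member of the Bcl2 family, was higher on the Bmi1-labelled (1.33) and Mel18-labelled (1.37) arrays, and Bcl2l11, another, was higher on the double-knockout-labelled array (1.03). Of the barrier genes, claudin Cldn4 read 671, 143, 194 and 732 in the same order of arrays, and Cldn2 read 714, 1624, 1071 and 313.

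Among signalling genes, Hes1, a Notch target, was higher on the Bmi1-labelled (1.10) and Mel18-labelled (1.05) arrays, with 0.35 on the double-knockout-labelled array. Ptch1, a Hedgehog receptor, differed by 1.04, 0.77 and -0.10, and Grem1, a BMP antagonist of the stroma, by -1.16, -0.77 and -0.07. Neither the Notch nor the Hedgehog and BMP list stood apart on any knockout array against wild type, although without a floor the Hedgehog and BMP list lay at percentile 98.47 on the Mel18-labelled array. Among Polycomb subunits, Pcgf1 was higher on the Bmi1-labelled array (1.20), Cbx8 on the Mel18-labelled array (1.13), and Kdm2b was lower on the double-knockout-labelled array (-1.09). The PRC1 list lay at 0.40, 0.30 and 0.03 and the PRC2 list at 0.23, 0.12 and -0.12, all inside the random range, although without the probe sets of the types that can hybridise to several transcripts the PRC2 list lay at percentile 1.81 on the double-knockout-labelled array. Hox genes as a whole lay inside the random range on the 3 arrays, though not with the floor at percentile 75 on the double-knockout-labelled array (percentile 1.56), nor on the Bmi1-labelled array without a floor (97.61) or after quantile normalization (97.65), where they lay higher, with Hoxd10 at 0.66, 0.68 and -1.64. The housekeeping list lay inside it too, at 0.22, 0.17 and -0.03.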
